A study of Arabidopsis thaliana with 36 samples.

How the data were processed

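Arabidopsis thaliana Col-0 and mutant or transgenic seedlings were profiled in 36 samples of 15 groups by RtcB sRNA-seq, cP-sRNA-seq and poly(A) mRNA-seq, grouped by the labels' titles and genotypes. The small RNA files are tag tables: the deposited values are counts of reads per distinct sequence, 1 library per table, from adapter-trimmed reads, with the RNA linker still on the RtcB reads. The 2 mRNA tables hold FPKM per gene and library as deposited by the authors; further scaling between libraries is not stated. Bowtie, Trimmomatic 0.36 and Cuffdiff are named without a role in the submitters' processing notes, with build TAIR10. In the table of the CYP71A13 and STTM-Ala-1 lines the Col-0 columns were assigned to the 2 Col-0 groups by their headers and group sizes; the labels number these samples otherwise, so replicate numbers of these columns are the table's own. Gene names came from a reference table of assembly TAIR10.1, used for names only: 32810 of 33557 gene identifiers matched a locus tag and 10647 had a symbol of their own. All 193 listed genes were in both tables.

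No genome came with the series, so tRNA 5′ fragments were found from the tags themselves. RtcB reads were kept where the linker TCACCGTGGT was present (45.3% to 46.9% of reads) and cut before it. Tags of 15 to 40 nt were grouped by their first 15 nt, exactly, rather than matched over their full length to tRNA genes as first designed. Candidate groups held at least 1000 tags in the Col-0 cP libraries together, the unnumbered one included. Those with tRNA-like signatures were extended through overlapping tags until the anticodon arm could be read, which named 63 of 101 tRNA-like families as 33 isoacceptors. This naming rule was adjusted after tags had been looked at and before any test between groups: a pyrimidine requirement was added, all uninoculated libraries rather than Col-0 alone were used for extension, the support for an extension was lowered to 3 tags, and 1 base of the 3′ strand of the anticodon arm was accepted, since the most abundant alanine-like family was otherwise unnamed. A stricter rule that needs 2 bases names 60 families and is reported as an alternative. Anticodons are as read in the tags, which are copies of RNA in which an inosine reads as G, so a family named Ala-GGC may belong to a tRNA with the gene anticodon AGC, and genome compartments, 3′ fragments and internal fragments, which the design named, were not resolved. 5′ tsRNAs are tags of 15 to 27 nt and long 5′ fragments tags of 28 to 40 nt. For the library without a replicate number, Wilson intervals at 95% are given, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

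Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with all 15 to 40 nt tags as library size, no further scaling, the 10 numbered cP libraries in 1 fit and features with at least 10 counts in at least 2 libraries, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The SE of a fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.454. log2(FPKM + 1) was tested with limma 3.58.1 with a trend, for genes with a mean of at least 1 FPKM over a table's libraries, all groups of a table in 1 fit. The 12 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the 12, beside an estimated correlation and fry. They are camalexin biosynthesis, indole glucosinolate and tryptophan synthesis, salicylic acid defence, jasmonate and ethylene defence, early pattern-triggered immunity, small RNA machinery, the RNase T2 family, phosphate starvation, photosynthesis, root cell markers, the circadian clock, and heat, cold and water stress. Named genes were the altered gene, the camalexin list, the 8 largest changes in each direction past the threshold that did not overlap and averaged at least 5 FPKM, and up to 3 members past the threshold of each other list. The genes singled out for the clock, root markers and shared calls beyond that rule were chosen after their values were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and DESeq2 1.42.0 were also used.

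The tests were run on simulated data with known answers. For rns1-3 against Col-0 in cP-sRNA-seq, with 66 features, 93.0% of 4-fold changes were recovered and 1.27% of unchanged features called at a biological coefficient of variation of 0.316, but 44.5% and 0.784% at the fitted 0.454. For mRNA, 200 changed genes were drawn only from those above 5 FPKM in Col-0. Of these, 2-fold and 4-fold changes were recovered at 84.6% and 98.6% in the rns1-3 setting among at least 17978 genes. In the STTM-Ala-1 setting they were recovered at 65.2% and 91.0% among at least 17862 genes. Recovery of weaker genes was not simulated.

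Replicate numbers were checked for pairing by correlating deviations from group means. Col-0 and rns1-3 mRNA libraries of the same number correlated at 0.290, 0.260 and 0.467, all above 0.1, which by the rule pairs them, though no label says why. Col-0 and rns3-2 mRNA libraries correlated at 0.0522, -0.00741 and 0.0563, which do not pair. The cP groups of 2 correlated with Col-0 at 0.154 (AGO1), 0.515 (B. cinerea), 0.563 (rns1-3) and 0.734 (rns3-2). These values are above 0.1 too, so a difference between replicate numbers may add to the spread of the cP groups. Between other cP groups values went down to -0.100. The main fits have no block, as designed before the data were examined. Relative mRNA depth was the most common ratio, within 0.02 in log2, of values under 0.5 FPKM to those of a table's first Col-0 library; FPKM here are estimates and not whole reads, so a minority of genes shares it. Overlaps of the 2 rns mutants, which share their Col-0 libraries, were set beside 100 simulations of unchanged groups. Alternatives were other scalings, filters, pseudocounts, tools, length classes, denominators, a replicate block, the 2 groups alone and each library left out; a change of sign was counted as reversed only where either fit passed the threshold. The other Col-0 group, the stricter naming rule, the 2-group block, the block on shared calls, the block by the table's own numbers, the division of Col-0 between the rns mutants and the omission of both libraries numbered 3 were added after seeing the data. Tag tables from all 14 small RNA libraries were used. The library without a number helped to choose and name tRNA families, and otherwise entered only 1 alternative and the observations.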

Results

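Small RNAs and mRNAs were measured in 14-day-old Arabidopsis thaliana seedlings kept at 22 °C under days of 16 h light with 8 h nights. RtcB sRNA-seq, in which the ligase RtcB joins an RNA linker to RNAs with a 2′,3′-cyclic phosphate or 3′-phosphate end, was done on 3 samples of the wild type Col-0. cP-sRNA-seq, which selects RNAs with a 2′,3′-cyclic phosphate, was done on 2 samples each of Col-0, the RNase T2 mutants rns1-3 and rns3-2, Col-0 seedlings inoculated with the fungus Botrytis cinerea, and small RNAs bound to ARGONAUTE1 (AGO1) in Col-0, and on 1 further Col-0 sample that carried no replicate number. Poly(A) mRNA-seq covered rns1-3, rns3-2, cyp71A13-1 and the overexpressor 35S:CYP71A13 with 3 samples each, STTM-Ala-1, whose name denotes a target mimic against the tRNA-Ala fragment, with 2 samples, and 3 groups of Col-0, with 3 samples named for the rns mutants, 3 for the CYP71A13 lines and 2 for STTM-Ala-1. The tag tables held between 7405362 and 15771747 tags of 15 to 40 nt per cP-sRNA-seq library and between 8583318 and 12097334 per RtcB library. The mRNA tables hold FPKM and no counts, so their total depth is unknown. Steps between values under 0.5 FPKM, shared by 9.82 to 32.8% of the low genes, put the depth of Col-0 replicates 2 and 3 named for the rns mutants at 0.946 and 1.636 of replicate 1, rns1-3 at 1.54 to 1.77 and rns3-2 at 1.765 to 1.959, so 2 of these 3 Col-0 libraries were read less deeply than the mutants. In the other table depth ran from 0.853 to 1.636 of its first Col-0 library. Whether depth moved any call was not tested. mRNA fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Errors are SD unless named, and log2 fold changes carry standard errors (SE). Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

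The first comparison asked how much of the Col-0 small RNA pool came from tRNA 5′ ends, the class that RtcB sRNA-seq was designed to profile. The shares count named families only, so tags of unnamed tRNA families are missing from them. Families were chosen by their tags in Col-0 cP libraries, so any abundant only in RtcB libraries are missing too. Fragments of 15 to 27 nt that begin at the tRNA 5′ end, called 5′ tsRNAs here, made up 23.9% ± 0.301 of RtcB tags (n = 3) and 17.03% ± 5.66 of cP-sRNA-seq tags (n = 2). Tags of 28 to 40 nt that begin there, called long 5′ fragments here, made up 32.9% ± 0.481 of RtcB tags and 26.7% ± 0.512 of cP tags. Long 5′ fragments of Val-TAC and Leu-TAA were 0 in every cP library, although their 5′ tsRNAs were present there. In RtcB libraries they were 0.622% to 0.632% and 0.172% to 0.174% of tags. Whether both kinds of tag table were filtered alike is not known, so their shares may have unlike denominators. The 5′ tsRNA-Ala group, all alanine tRNAs together, made up 5.21% ± 0.0669 of RtcB tags and 7.60% ± 3.47 of cP tags, whereas alanine long 5′ fragments made up 0.0418% ± 0.00188 and 0.0134% ± 0.00476. The most abundant alanine tag in cP Col-0 was GGGGATGTAGCTCAGATGGT, 20 nt long, from a tRNA whose anticodon was read as GGC, with 333800 tags. In RtcB libraries 19 nt was the most frequent length of 5′ tsRNA-Ala, with 54.4% to 54.8% of alanine 5′ tags, and in the 2 numbered Col-0 cP libraries it was 20 nt, with 32.6% and 34.0%. Among 5′ tsRNAs of cP Col-0, Gly-TCC held 5.59% ± 0.888 of all tags, Ala-GGC 5.31% ± 2.60, Ala-TGC 1.31% ± 0.450, Ala-CGC 0.972% ± 0.420 and His-GTG 0.751% ± 0.177. Among long 5′ fragments, Gly-TCC held 10.4% ± 2.45, Glu-TTC 9.56% ± 2.70, His-GTG 4.27% ± 0.680, Glu-CTC 0.894% ± 0.162 and Asp-GTC 0.732% ± 0.0175. The methods select different RNA ends in separate libraries, so no test was made between them, and the Col-0 cP libraries differed from each other by more in 5′ tsRNA-Ala, with 5.15% and 10.1%, than their mean differed from the RtcB mean. Shares of alanine tags depended on how tRNA families were named: with a stricter naming rule chosen after seeing the data, 5′ tsRNA-Ala was 2.88% of RtcB tags and 1.98% of cP tags, and all 5′ tsRNAs were 21.6% and 11.4%.

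**Figure D1:**
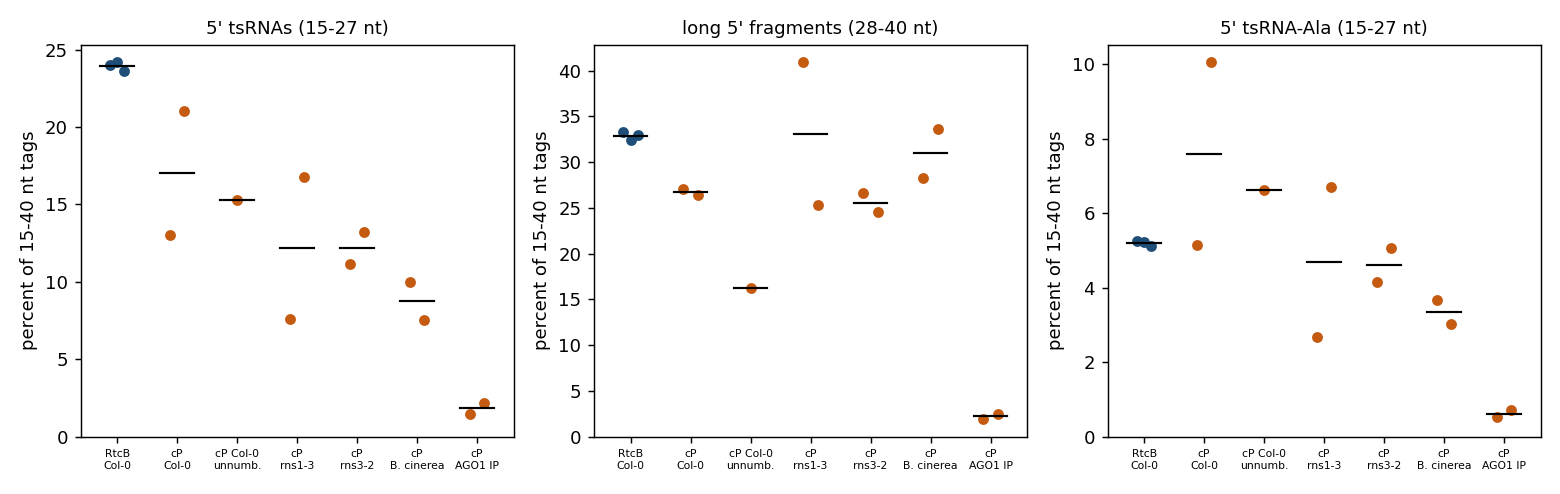
Percent of 15 to 40 nt tags that were 5′ tsRNAs, long 5′ fragments and 5′ tsRNA-Ala in each small RNA library (vertical axes in percent, one point per library, bars at group means). The AGO1 libraries lie lowest in each panel, at 0.519% and 0.715% for 5′ tsRNA-Ala.

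The AGO1 comparison asked which 5′ tRNA fragments were found with AGO1, the main small RNA effector of plants. Relative to all tags, 5′ tsRNA-Ala was 0.617% ± 0.138 of AGO1-bound tags and 7.60% ± 3.47 of Col-0 tags (n = 2 each), and it fell by 3.62 on the log2 scale (SE 0.51, adjusted p = 6.16e-09, edgeR quasi-likelihood test). Among 61 tRNA features, 59 were lower in AGO1 libraries and 0 were higher. The falls of called features ranged from 5.17 for the long 5′ fragments of Phe-GAA to 1.34 for the 5′ tsRNA of Glu-CTC: the 5′ tsRNAs of Gly-TCC fell by 3.18 (SE 0.51), of Ala-GGC by 3.62 (SE 0.53) and of Ala-TGC by 3.70 (SE 0.58), and the long 5′ fragments of Glu-TTC by 3.52 (SE 0.48), of Gly-TCC by 3.48 (SE 0.48) and of His-GTG by 4.22 (SE 0.52). Tags of 21 nt, the usual length of AGO1-bound microRNAs, were 10.9% ± 0.561 of AGO1 tags and 3.45% ± 0.465 of Col-0 tags. Scaled to the tRNA features themselves, the calls ended: with TMM 1 feature was called, the 5′ tsRNA of Glu-CTC, which was higher in AGO1 libraries (log2 fold change 1.84, SE 0.30, adjusted p = 0.00836), and 5′ tsRNA-Ala was at -0.37 (adjusted p = 0.594).

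The B. cinerea comparison asked whether infection changed 5′ tRNA fragments. After inoculation 5′ tsRNA-Ala was 3.34% ± 0.453 of tags against 7.60% ± 3.47 in uninoculated Col-0 (n = 2 each; log2 fold change -1.19, SE 0.47, adjusted p = 0.413), lower in both inoculated libraries than in either Col-0 library, an arrangement 2 against 2 gives often by chance. Glu-TTC long 5′ fragments were 17.02% ± 7.82 against 9.56% ± 2.70 (log2 fold change 0.83, SE 0.44, adjusted p = 0.413), and the 5′ tsRNA of Gly-TCC was 3.05% ± 1.04 against 5.59% ± 0.888 (-0.88, SE 0.47). The edgeR test called 0 of 61 features, with 6 at an unadjusted p under 0.05, and DESeq2 called 0. Without either library of a group in turn, the change of 5′ tsRNA-Ala ranged from -1.59 to -0.62. Among tags of repeated sequences, 0.00293% and 0.00307% in the inoculated libraries and 0.00597% and 0.000386% in Col-0 were absent from 5 other uninoculated libraries, so this measure showed no excess of new sequences after inoculation. It was 2.17% and 2.41% in the AGO1 libraries, which were not inoculated, so it moves with library type and is no measure of fungal RNA.

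The rns comparisons asked whether loss of RNS1 or RNS3, ribonucleases of the RNase T2 family, which the series' design text places among mutants for 5′ tsRNA biogenesis, altered the fragments. 5′ tsRNA-Ala was 4.69% ± 2.84 of tags in rns1-3 (log2 fold change -0.70, SE 0.47, adjusted p = 0.904) and 4.61% ± 0.663 in rns3-2 (-0.72, SE 0.47, adjusted p = 0.962), against 7.60% ± 3.47 in Col-0 (n = 2 each). The 2 rns1-3 libraries lay apart, at 2.68% and 6.69%. Without each library of the 2 groups in turn, the change ranged from -1.503 to -0.135 in rns1-3 and from -1.13 to -0.16 in rns3-2. Glu-TTC long 5′ fragments were 18.4% ± 11.4 in rns1-3, 10.97% ± 0.524 in rns3-2 and 9.56% ± 2.70 in Col-0. In edgeR 0 of 61 features passed in either mutant, with 1 at an unadjusted p under 0.05 in rns1-3 and 0 in rns3-2, and DESeq2 called 0. In simulated libraries with the spread fitted over all groups, the test for rns1-3 recovered 44.5% of 4-fold changes, so changes of that size can be missed. Replicates of rns1-3 and Col-0 differed by a median over features of 1.06 and 0.911 on the log2 scale. The other cP groups had 0.523 to 0.610, so recovery for rns1-3 may be lower than simulated. Without rns1-3 replicate 2, which leaves 1 rns1-3 library, the log2 fold change of Glu-TTC long 5′ fragments was 1.46. They were 26.4% and 10.3% of tags in the 2 rns1-3 libraries and 11.5% and 7.65% in Col-0. Between rns1-3 and rns3-2, 5′ tsRNA-Ala differed by 0.02 (SE 0.46), and 0 features were called, with 0 at an unadjusted p under 0.05.

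The rns mRNA comparisons asked which genes changed when RNS1 or RNS3 was disrupted. The targeted genes were weakly expressed: RNS1 (AT2G02990) was listed at 0 in the 3 rns1-3 libraries and at 0, 0.343 and 0.0985 FPKM in Col-0, too low to check the label, and RNS3 (AT1G26820) was 3.46 ± 1.31 FPKM in rns3-2 against 4.51 ± 1.01 in Col-0 (n = 3, adjusted p = 0.819), which does not separate the rns3-2 libraries from Col-0.

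In rns1-3, plant defensin genes rose. PDF1.2c (AT5G44430) rose from 133 ± 26.9 to 964 ± 227 FPKM (log2 fold change 2.84, SE 0.20, n = 3), PDF1.2a (AT5G44420) from 310 ± 93.4 to 2001 ± 380.1 (2.72, SE 0.23), PDF1.2b (AT2G26020) from 124 ± 25.4 to 819 ± 235 (2.70, SE 0.22) and PDF1.3 (AT2G26010) from 179 ± 50.4 to 713 ± 212 (1.98, SE 0.27). With replicate numbers as a block, which pair rns1-3 with Col-0 here, PDF1.3 did not pass (adjusted p = 0.0672). These are antifungal peptides induced by jasmonate and ethylene, and the 4 genes are near-identical copies, so reads may be shared among them. Among the Col-0 libraries named for the CYP71A13 lines PDF1.2a ran from 14.1 to 1744 FPKM, so it can vary widely between wild-type samples. The chitinase PR3 (AT3G12500) rose from 8.78 ± 1.77 to 26.1 ± 3.53 (1.48, SE 0.16), the chitinase-family genes AT2G43580 and AT2G43590 by 2.60 and 1.71, and NATA1, an acetyltransferase of jasmonate responses, by 1.77. AT1G67105 fell from 5.01 ± 1.89 to 0.899 ± 0.0606 FPKM. Of the jasmonate and ethylene defence list, 4 of 23 members rose, 14 rose adjusted over the list alone, 22 were higher, and the median log2 fold change was 0.54 (adjusted p = 2.45e-28, and 0.00252 with an estimated correlation). Camalexin is the main antifungal phytoalexin of Arabidopsis: all 12 genes of its list were higher, none past the threshold for single genes, with a median of 0.33 (adjusted p = 3.85e-06, and 0.0303 with an estimated correlation). CYP71A13, a cytochrome P450 of that pathway, was 9.63 ± 4.14 against 5.07 ± 0.228 FPKM (0.73, SE 0.25, adjusted p = 0.969). In rns3-2 CYP71A13 was 8.76 ± 1.59 FPKM, so the higher level was not particular to rns1-3. The indole glucosinolate list was higher (10 of 12 members, adjusted p = 0.00214, but adjusted p = 0.105 with an estimated correlation), and the photosynthesis list lower (17 of 19 members, adjusted p = 0.02004, but adjusted p = 0.479 with an estimated correlation). The other 8 lists did not pass (adjusted p from 0.165 to 0.986). In all, limma called 16 of 18254 genes, 15 higher and 1 lower, and 1276 genes had non-overlapping groups, fewer than the 10% that chance gives. The count was 45 without Col-0 replicate 3, 5 without Col-0 replicate 2, 10 without Col-0 replicate 1, 7 without rns1-3 replicate 1 and 9 without rns1-3 replicate 2. With the block and the 2 groups alone, a fit chosen after seeing the data, 7 genes were called, and PR3 (adjusted p = 0.118), AT2G43580 (0.138), AT4G16260 (0.122), PDF1.3 (0.122), BAM5 (0.118), VSP2 (0.297), PGDH (0.332) and AT1G67105 (0.140) did not pass.

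In rns3-2, the same pathway rose further. PDF1.2c reached 1899.9 ± 92.0 FPKM (log2 fold change 3.85, SE 0.20), PDF1.2a 3363 ± 380.2 (3.48, SE 0.23) and PR3 79.3 ± 11.5 against 8.78 ± 1.77 (3.05, SE 0.16). The osmotin gene OSM34 rose from 3.87 ± 1.46 to 66.3 ± 5.89 (3.82, SE 0.26), AT4G33720, a pathogenesis-related protein family member, from 0.0863 ± 0.149 to 30.4 ± 2.83, and NATA1 from 3.16 ± 0.732 to 43.2 ± 6.21 (3.42, SE 0.22). The abscisic acid and drought genes RAB18 and RD29B rose by 2.36 (SE 0.16) and 2.24 (SE 0.20). LOX1 fell from 8.64 ± 1.41 to 2.83 ± 0.0915 (-1.32, SE 0.17), and UBC11 fell by 0.87. All 23 members of the jasmonate and ethylene list were higher, 8 rose, 16 rose adjusted over the list alone, and the median was 0.63 (adjusted p = 2.29e-30, and 0.00207 with an estimated correlation). The heat, cold and water stress list was higher (2 of 16 rose, adjusted p = 4.70e-07, and 0.0466 with an estimated correlation). The salicylic acid list was lower (14 of 16 members, adjusted p = 2.54e-05, but adjusted p = 0.318 with an estimated correlation), as was the small RNA machinery list (13 of 16, adjusted p = 0.00496, but adjusted p = 0.318 with an estimated correlation). The other 8 lists did not pass (adjusted p from 0.180 to 0.804). In all, 67 of 18254 genes were called, 61 higher and 6 lower, with 2528 not overlapping where chance gives 10%. The count was 112 without Col-0 replicate 3, and 28, 30 and 28 without rns3-2 replicates 1, 2 and 3.

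Both mutants shared 15 calls, 14 higher and 1 lower. In 100 simulations of unchanged groups with the shared Col-0 the means were 0 and 0.02, and the most were 0 and 1. The 1 lower gene is no more than these gave. Unchanged groups yield few calls at all, so the simulations do not show what the shared Col-0 adds where a mutant does differ. With the replicate block, which pairs rns1-3 with Col-0, 9 of the 15 were still called in rns1-3, and PDF1.3 (adjusted p = 0.0672), VSP2 (0.0657), BAM5 (0.0578), AT3G12502 (0.0578), AT1G73780 (0.0554) and PGDH (0.104) were not. With the block and the 2 groups alone 6 of the 15 were called. The 15 were PDF1.2a, PDF1.2b, PDF1.2c, PDF1.3, PR3, VSP2, NATA1, BAM5, PGDH, AT2G43580, AT2G43590, AT4G16260, AT1G73780 and AT3G12502 among those higher, and AT1G67105 lower. Fold changes of the mutants correlated at r = 0.683 across genes, against 0.499 simulated from the shared Col-0 libraries alone, and the covariance exceeded the simulated one by 0.0258. With the Col-0 libraries divided so that the mutants shared none, 1 for either mutant and 2 for the other, an alternative chosen after seeing the data, r ran from 0.0421 to 0.234 and the covariance from 0.00461 to 0.0253 over the 6 divisions, against 0.0483 with shared Col-0. Fewer Col-0 libraries add noise, which lowers r but not the covariance, so much of the correlation came with the shared Col-0, and what remained across all genes was weak. Neither the simulations nor the divisions take account of the pairing of rns1-3 with Col-0 by number, so the size of what remained is uncertain. Genes are not independent replicates. Tested directly, 21 genes differed between rns1-3 and rns3-2, 2 higher and 19 lower in rns1-3: OSM34 was 8.46 ± 3.09 against 66.3 ± 5.89, RAB18 14.5 ± 2.90 against 57.9 ± 1.46, PR3 26.1 ± 3.53 against 79.3 ± 11.5, and LOX1 11.5 ± 2.62 against 2.83 ± 0.0915 FPKM.

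**Figure D2:**
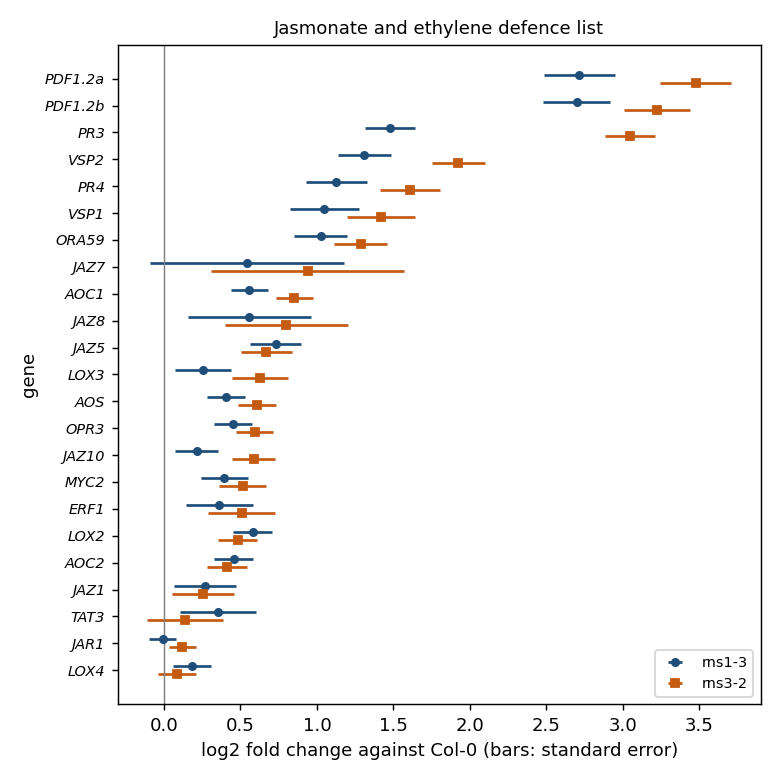
Log2 fold change against Col-0 (horizontal axis, with SE) of the 23 genes of the jasmonate and ethylene defence list in rns1-3 (circles) and rns3-2 (squares). PDF1.2a, at 2.72 and 3.48, has the largest change in both mutants, and all genes lie above 0 in rns3-2.

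The 35S:CYP71A13 comparison asked what overexpression of CYP71A13 changed. CYP71A13 (AT2G30770) itself rose from 2.22 ± 1.62 to 64.8 ± 26.1 FPKM (log2 fold change 4.40, SE 0.45, n = 3). Of the camalexin list, 4 of 11 members rose and 4 fell: CYP71B15, the last enzyme of the pathway, rose from 1.24 ± 0.493 to 4.83 ± 1.63 (1.36, SE 0.24) and GSTF6 by 1.81 (SE 0.37), while CYP79B2 and CYP79B3, which supply the pathway's oxime, fell by 0.63 and 0.76. The jasmonate and ethylene list was higher (14 of 21 rose, median 1.44, adjusted p = 0.00171, but adjusted p = 0.703 with an estimated correlation), with PR3 rising from 0.569 ± 0.580 to 24.3 ± 8.38 and VSP2 from 4.19 ± 5.22 to 68.4 ± 27.3. The heat, cold and water stress list was higher (11 of 19 rose, adjusted p = 0.0189, but adjusted p = 0.703 with an estimated correlation), with LTI30 rising from 12.8 ± 8.64 to 189 ± 51.7. The photosynthesis list was lower (16 of 19 fell, adjusted p = 4.35e-05, but adjusted p = 0.703 with an estimated correlation), with RBCS2B falling from 8290.2 ± 873 to 2364 ± 299.5, a small subunit gene that may share reads with its copies. The fall of the photosynthesis list was lost under quantile normalization, and against the other Col-0 group of the table, chosen after seeing the data, the list was higher (adjusted p = 0.0101). Clock genes were among the largest changes: LHY, a morning-expressed regulator, fell from 206 ± 6.39 to 5.17 ± 0.629, CCA1 from 197 ± 9.32 to 10.0 ± 0.695, and PRR5, of the later day, rose from 4.02 ± 4.64 to 82.9 ± 1.301. In all, limma called 8105 of 18146 genes, 3966 higher and 4139 lower, 2719 of them by 2-fold or more, and 10111 genes did not overlap where chance gives 10%. The 2 Col-0 groups of this table differ in 8699 genes. Against that other Col-0 group, an alternative chosen after seeing the data, PR3 was at -0.44, CYP71B15 at -0.13 and ABCG34 at -0.82, and 5258 genes were called. The other 9 lists did not pass (adjusted p from 0.140 to 0.969).

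**Figure D3:**
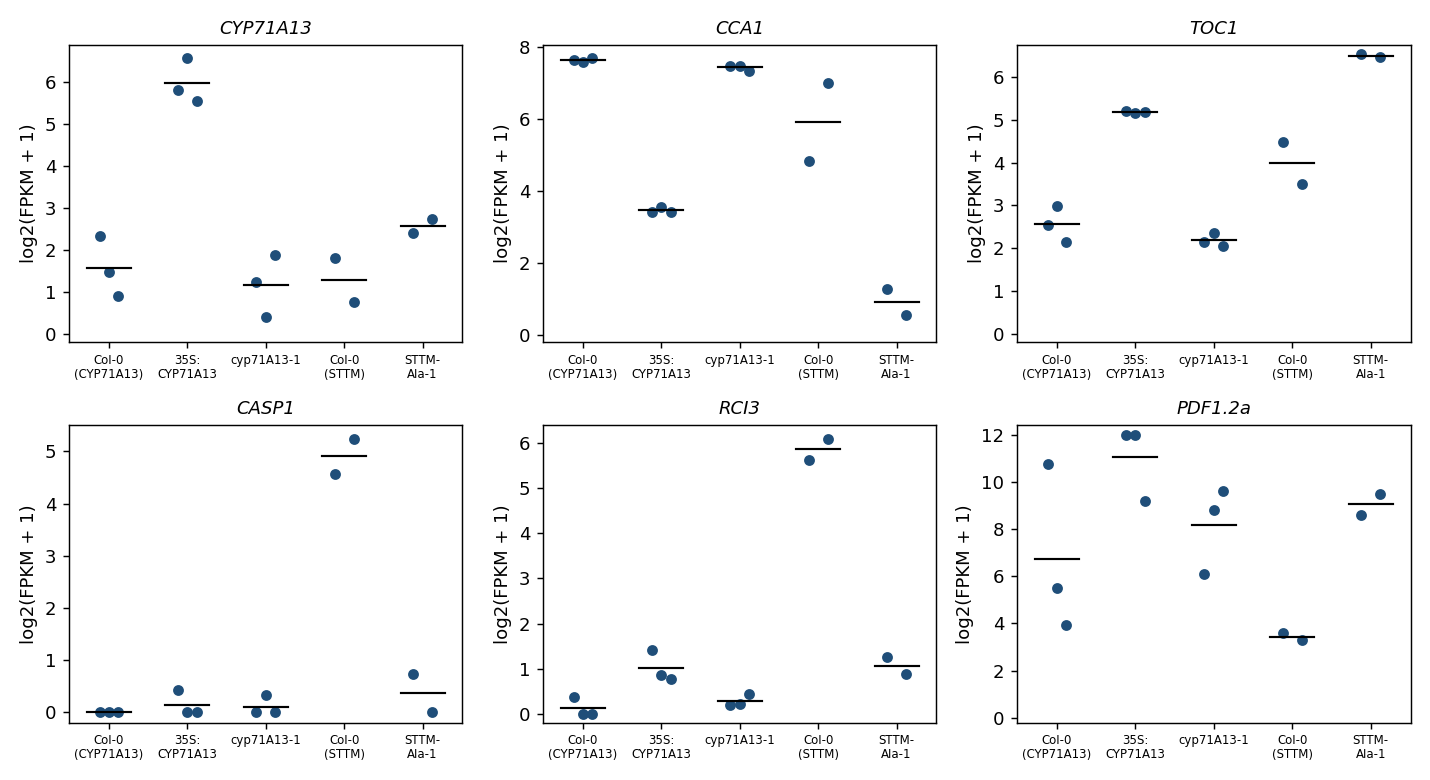
Log2(FPKM + 1) per library (vertical axes, one point per library, bars at group means) of 6 genes in the 35S:CYP71A13 and STTM-Ala-1 table. CYP71A13 stands at 45.5 to 94.4 FPKM in 35S:CYP71A13, and CASP1 averages 29.8 FPKM in the Col-0 libraries named for STTM-Ala-1 and at most 0.327 in the other groups.

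The cyp71A13-1 comparison asked what loss of CYP71A13 changed. CYP71A13 was 1.45 ± 1.18 FPKM in cyp71A13-1 against 2.22 ± 1.62 in Col-0 (n = 3, adjusted p = 0.911), so its level does not separate the libraries labelled cyp71A13-1. Of the camalexin list, 10 of 11 members were lower, none past the threshold, and CYP71B15 was 0.289 ± 0.171 against 1.24 ± 0.493. BBX31, a B-box transcription factor, rose from 2.49 ± 1.94 to 27.6 ± 0.952 FPKM (log2 fold change 3.23, SE 0.37), AT2G11410 from 0.0102 ± 0.0177 to 5.49 ± 0.149, AT3G55920 from 2.23 ± 0.496 to 13.2 ± 0.354, AT3G05170 by 2.00 and AT3G21950 by 1.73. MAF5, a flowering-time repressor, fell from 7.35 ± 3.40 to 0.599 ± 0.262 (-2.29, SE 0.31). The heat, cold and water stress list was lower (15 of 19 members, adjusted p = 0.00843, but adjusted p = 0.318 with an estimated correlation), and so was the circadian clock list (14 of 15, adjusted p = 0.0258, but adjusted p = 0.228 with an estimated correlation). In all, limma called 8 of 18146 genes, 7 higher and 1 lower, with 1355 at an unadjusted p under 0.05, and 2250 genes did not overlap where chance gives 10%. The count was 265 without Col-0 replicate 1, and 4, 5 and 4 without cyp71A13-1 replicates 1, 2 and 3. The other 10 lists did not pass (adjusted p from 0.219 to 0.847).

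The STTM-Ala-1 comparison asked what a target mimic against the tRNA-Ala fragment changed. PDF1.2a rose from 9.96 ± 1.60 to 548 ± 224 FPKM (log2 fold change 5.59, SE 1.86, n = 2), COR27, a cold-regulated gene, from 0.971 ± 1.197 to 162 ± 18.6 (6.51, SE 0.42), and PR2 from 3.25 ± 3.21 to 54.0 ± 15.3 (3.91, SE 0.63). In the Col-0 libraries named for the CYP71A13 lines PDF1.2a was 1744, 44.7 and 14.1 FPKM. That range spans both STTM-Ala-1 libraries, at 390 and 707 FPKM. The salicylic acid list was higher (6 of 14 rose, adjusted p = 0.00184, but adjusted p = 0.266 with an estimated correlation), with PR5 rising from 9.58 ± 1.52 to 63.4 ± 4.74. Root cell markers fell: 7 of 8 members, median -3.69 (adjusted p = 1.25e-06, but adjusted p = 0.0672 with an estimated correlation), with CASP1 from 29.8 ± 10.2 to 0.327 ± 0.462 and RCI3 from 58.3 ± 13.4 to 1.12 ± 0.407. Phosphate starvation genes fell as well (8 of 13, adjusted p = 0.000757, but adjusted p = 0.0507 with an estimated correlation), with PHT1;1 from 35.5 ± 13.1 to 0.264 ± 0.0243. The photosynthesis list was lower (15 of 19 fell, adjusted p = 3.86e-06, but adjusted p = 0.390 with an estimated correlation), with LHCB2.1 and LHCB2.2 each falling by 4.55, copies that may share reads. CCA1 fell from 76.4 ± 69.0 to 0.957 ± 0.683. Dusk-phased clock genes were above dawn-phased ones by a median of 5.56, a test chosen after the values were seen. A different time of day at harvest may therefore account for some of the changes in STTM-Ala-1. CYP71A13 was 4.97 ± 0.928 FPKM in STTM-Ala-1, 1.60 ± 1.29 in its Col-0 and 2.22 ± 1.62 in the Col-0 named for the CYP71A13 lines. AT3G41768 and AT1G53542 were listed at 0 in both STTM-Ala-1 libraries. In all, limma called 5860 of 18146 genes, 2314 higher and 3546 lower, and 11825 did not overlap, where chance gives 33.3%. Against the other Col-0 group, an alternative chosen after seeing the data, CASP1 was at 0.36, RCI3 at 0.94 and PHT1;1 at 0.04, and 9730 genes were called. Of the 4 lists only photosynthesis passed there (adjusted p = 6.92e-11), and the salicylic acid (0.392), phosphate starvation (0.325) and root marker lists (0.961) did not. Leaving out STTM-Ala-1 replicate 1 or 2 gave 3802 or 3873. With quantile normalization the median of all genes moved from -0.06 to 0.08 and the calls were 3812 higher and 2993 lower. The other 8 lists did not pass (adjusted p from 0.0908 to 0.586).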

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

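All tests of explanations in this part, with their bounds, were chosen after the results they use had been seen, so they can argue against an explanation but do not establish one.

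Effects of rns1-3 and rns3-2 differed when tested against each other: 21 genes were called, and the salicylic acid (adjusted p = 1.23e-08, 0.131 with an estimated correlation), camalexin (0.000205; 0.0483), early immunity (0.00373; 0.0483) and small RNA machinery lists (3.18e-05; 0.113) were higher in rns1-3. The jasmonate and ethylene (adjusted p = 1.02e-06, 0.0483 with an estimated correlation), heat, cold and water stress (9.91e-07; 0.0483) and photosynthesis lists (4.31e-05; 0.135) were lower in rns1-3.

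The first pattern is the 8105 genes called in 35S:CYP71A13. Dusk-phased clock genes were above dawn-phased ones by a median of 5.68 on the log2 scale (7 genes each, 13 of 14 called), against -0.29 in cyp71A13-1, so a different time of day at harvest may account for part of it; the labels give no harvest time. Fold changes of 35S:CYP71A13 against cyp71A13-1 correlated across genes at r = 0.537 with those between the 2 Col-0 groups, which share no library with them, as a difference between library batches needs. The 2 Col-0 groups also differ in clock genes (dusk minus dawn 2.91, 10 of 14 called), so this correlation goes equally with a difference in harvest time and does not separate the 2 explanations. The CYP71A13 level stays open: 44.0% of the calls moved the opposite way in cyp71A13-1, which shares the control and in which CYP71A13 itself was not called.

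The second pattern is the fall of root cell markers in STTM-Ala-1. Of the 8 markers all but SCR were higher in the Col-0 libraries named for STTM-Ala-1 than in the other Col-0 group, by a median of 3.69 over the 8, with CASP1 at 29.8 against 0 FPKM, RCI3 at 58.3 against 0.101 and PRP3 at 34.9 against 0.0493, so more root tissue in those Col-0 libraries is a candidate explanation; SHR and SCR, also on the list, are expressed in both groups. Against the other Col-0 group the markers in STTM-Ala-1 were at a median of 0.0658, in both directions, which leaves an effect of the genotype open, since that group differs from STTM-Ala-1 in other ways too.

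The third pattern is the rise of the jasmonate and ethylene list in both rns mutants. A single library is argued against: with an estimated correlation, the largest adjusted p of the list without any 1 library was 0.0276 in rns1-3 and 0.0184 in rns3-2. A different time of day at harvest stays open: dusk-phased minus dawn-phased clock genes differed by -0.19 in rns1-3 and 0.11 in rns3-2, but the dawn-phased genes were weakly expressed and these differences lie within the error of the genes. Less 5′ tsRNA-Ala in the mutants stays open as well: it passed in neither (smaller adjusted p = 0.904), with 2 libraries a group. Handling, batch and the mutations themselves were not tested apart.

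With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, the real count and the highest of the other splits were 8105 and 1 for 35S:CYP71A13 (1 split as large, the real one), 8 and 90 for cyp71A13-1 (2 splits), 16 and 70 for rns1-3 (2 splits), 67 and 1 for rns3-2 (1 split), and 21 and 0 for rns1-3 against rns3-2 (1 split). For lists they were 3 and 3 (3 splits), 2 and 5 (6 splits), 4 and 4 (3 splits), 4 and 3 (1 split), and 7 and 3 (1 split). The split with 90 genes sets Col-0 replicate 1 with cyp71A13-1 replicates 2 and 3, and the one with 70 sets Col-0 replicate 1 with rns1-3 replicates 1 and 2, so these libraries differ in a way other than genotype. The latter split keeps both libraries numbered 3 on 1 side, in line with the pairing of these numbers. Among the 4 splits that part all 3 numbers of rns1-3 and Col-0, as the real one does, the highest other count was 1 against 16; with the block and the 2 groups alone 7 genes were called.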

How the results depend on the processing

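The other Col-0 group, the stricter naming of tRNA families, the 2-group block, the block on shared calls, the block by the table's own numbers, the division of Col-0 between the rns mutants and the omission of both libraries numbered 3 were chosen after seeing the data. The other alternatives were chosen before. Causes were not tested unless the alternative's construction shows them. The AGO1 calls depend on scaling: with TMM, DESeq2 size factors or the tRNA tags as library size, 1 feature was called each, the 5′ tsRNA of Glu-CTC, which was higher (1.84, 1.85 and 2.097), and 5′ tsRNA-Ala was at -0.37, -0.37 and -0.16 (adjusted p = 0.594, 0.582 and 0.989), since such scaling takes up a shift common to the tRNA features. With the tRNA tags as library size Ala-GGC long 5′ fragments were at 0.19, Gly-TCC 5′ tsRNAs at 0.23 and all alanine long 5′ fragments at 0.10. Left out one at a time, AGO1 counts ranged from 49 to 61 and rns1-3 feature counts from 0 to 1, and 5′ tsRNA-Ala from -4.03 to -3.06 (AGO1), -1.59 to -0.62 (B. cinerea), -1.503 to -0.13 (rns1-3) and -1.13 to -0.16 (rns3-2), a lone library being assumed to vary like the other groups.

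Of Col-0 tags, with the tRNA tags as denominator the shares of 5′ tsRNAs, long 5′ fragments and 5′ tsRNA-Ala were 42.1%, 57.9% and 9.16% (RtcB) and 38.4%, 61.6% and 17.02% (cP). With classes of 15 to 25 and 30 to 40 nt they moved to 23.3% and 32.4% (RtcB 5′ tsRNAs and long 5′ fragments) and to 13.02% and 20.9% (cP), as fewer tags count. Stricter naming gave 21.6% and 11.4% (5′ tsRNAs, RtcB and cP), 2.88% and 1.98% (5′ tsRNA-Ala, RtcB and cP). Tags matching the genome were not run, as no genome was given; without one, all 15 to 40 nt tags are the library size reported.

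Genes called, left out one at a time, ranged from 5 to 45 (rns1-3), 28 to 112 (rns3-2), 6771 to 8004 (35S:CYP71A13), 4 to 265 (cyp71A13-1) and 3802 to 5839 (STTM-Ala-1), and lists from 3 to 5, 3 to 4, 3 to 3, 0 to 3 and 4 to 7. For rns1-3 a pseudocount of 5 gave 8 genes, no filter 9, no trend 10, the 2 groups alone 5, and both libraries numbered 3 left out 53. A mean of at least 5 gave 43 genes in rns3-2 and 3 in cyp71A13-1, where the 2 groups alone gave 5. STTM-Ala-1 had 3334 with the 2 groups alone. A fold of at least 2 gave 2719 (35S:CYP71A13) and 2714 (STTM-Ala-1), by construction. Lists called with an estimated correlation were 2, 2, 0, 0 and 0, and with fry 2, 2, 6, 0 and 8, in the order above. Under quantile normalization the photosynthesis list of 35S:CYP71A13 turned upward (adjusted p = 0.944). Without the first Col-0 library named for STTM-Ala-1, early immunity turned downward (adjusted p = 0.0153). Without the second it passed upward (adjusted p = 0.00166), and without STTM-Ala-1 replicate 2 it did not pass (adjusted p = 0.690).

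With the replicate block, 11 genes were called in rns1-3, whose numbers pair with Col-0, and 7 with the 2 groups alone; the lists stayed at 4. Of the 16 genes, 9 were still called and 2 others gained; PDF1.3 (adjusted p = 0.0672), VSP2, BAM5, AT3G12502, AT1G73780, PGDH and CYP81D1 did not pass, and the block changed no other call of these 16. With the 2 groups alone 6 of the 16 were called, and AT1G73780 fell under the filter. Shared calls numbered 11 under the block. The block gave 84 in rns3-2, 17 between the mutants, 61 features for AGO1 and 0 for the other cP comparisons, and lists of rns3-2 stayed at 4. AT2G18690 in rns3-2 (adjusted p = 0.0830) and TSPO between the mutants (adjusted p = 0.0890) did not pass under it; these samples share only a number, and not every library correlated best with its own. For 35S:CYP71A13, cyp71A13-1 and STTM-Ala-1 no paired analysis was possible by the labels' numbers, which differ from those of their Col-0. By the numbers of the table's own columns, libraries correlated with Col-0 at -0.0266 to 0.112, -0.202 to -0.0411 and -0.0301, which pairs none. A replicate block by these numbers gave 7647, 6 and 5355 genes and 3, 2 and 4 lists; PR1 (adjusted p = 0.0647) and PDF1.2a (0.0627) in 35S:CYP71A13, MAF5 (0.271) in cyp71A13-1, and DCL2 (0.0669) and PDF1.2a (0.0666) in STTM-Ala-1 did not pass, and CYP71A12 (0.0237) passed in 35S:CYP71A13.

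Against the other Col-0 group, 35S:CYP71A13 had 5258 genes and 8 lists, and STTM-Ala-1 9730 genes and 1 list. In 35S:CYP71A13 the log2 fold changes that turned were RCI3 -4.86, RNS4 -1.20, IGMT1 -0.85, AGO7 0.12, AT2G33850 -0.25, ABCG34 -0.82, GDPD1 -1.59, AT3G05727 -0.50, PR3 -0.44, CYP71B15 -0.13, ERF6 -1.09, AT4G22485 -0.58, AT4G22505 -0.75, WRKY53 -0.41, AT4G29030 -0.71, GGP1 0.0684, BAK1 -0.24, KIN1 -0.24, RBCS1B 0.10 and AGO10 -0.30; the photosynthesis list turned upward (adjusted p = 0.0101) and root markers downward (1.64e-08). In STTM-Ala-1 they were RCI3 0.94, RNS4 0.88, AT1G23720 0.37, CYP71A12 1.31, CASP1 0.36, ABCG34 1.23, DCL2 0.23, AT3G28550 0.0950, AT3G54580 0.27, PRP3 0.13, AT4G15390 0.0316, WRKY29 0.27 and PHT1;1 0.0439, and root markers turned upward (adjusted p = 0.961). Among single genes and features, 3289 values kept direction and side of the threshold, 277 fell below it, 8 passed it and 36 reversed; among lists these were 628, 31, 20 and 5. FPKM without counts leaves the total depth of the mRNA tables unknown; relative depth, from steps of low values, ran from 0.946 to 1.959 of the first Col-0 library in the rns table and from 0.853 to 1.636 in the other, and calls were not tested against it. With the rns mutants set against separate Col-0 libraries, added after seeing the data, their fold changes correlated at 0.0421 to 0.234.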

Other observations

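The Col-0 cP-sRNA-seq library without a replicate number, which entered 1 alternative of the comparisons only, held 15.3% 5′ tsRNAs (95% Wilson interval 15.277 to 15.319), 16.2% long 5′ fragments (16.187 to 16.230) and 6.64% 5′ tsRNA-Ala (6.621 to 6.650) among 11056867 tags. Its most frequent alanine length was 19 nt, with 44.7% of alanine 5′ tags, as in the RtcB libraries.

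The Col-0 libraries named for STTM-Ala-1 differed from each other in clock genes: CCA1 was 27.6 and 125 FPKM, LHY 7.62 and 134, and PRR5 22.3 and 2.82. Of the RNase T2 family, RNS2, RNS3 and RNS4 fell in STTM-Ala-1 by 0.44, 0.94 and 0.91, although the list did not pass (adjusted p = 0.0908). Against the other Col-0 group, chosen after seeing the data, RNS4 was at 0.88, RNS3 at -0.05 (4.69 against 4.91 FPKM) and RNS2 at -0.38.

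In STTM-Ala-1, dusk-phased clock genes were above dawn-phased ones by a median of 5.56, with 12 of 14 called, a test chosen after the values were seen. A different time of day at harvest may therefore account for part of the 5860 calls, although the 2 Col-0 libraries differ from each other in these genes and the labels give no harvest time.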
